A study of Mus musculus with 2 samples.

How the data were processed

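MicroRNA-seq libraries, which sequence small RNA, were made from the adrenal gland of male B6CASTF1/J mice at postnatal day 14, per the labels. The labels give 1 group of 2 libraries, numbered biological replicates 1 and 2. They came from different biosamples that each name 3 males and share 1 donor record, so whether each library pools several animals is not given in the sources used here. The labels give a size range below 30, without a unit.

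The deposited values are raw read counts per annotated miRNA gene, 1 file per library and not normalized. The deposited notes on these files name the mm10 assembly and GENCODE M21. The aligner, the counter and their versions are not given in the sources used here. Each file holds 2202 miRNA genes in 3 count columns without a header, preceded by 4 summary rows. From the deposited values, the first column counts reads of either strand, the second those on the strand of the gene and the third those on the opposite strand. The second was used here. A gene is a hairpin, so the 2 arms of a precursor were not separated. Reads counted as mapping to several places are in no gene.

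All 2202 gene identifiers matched GENCODE M21, which gave symbols, positions and overlapping genes. Hairpin sequences came from the transcripts of that annotation. The summary rows name no gene and stayed out of library sizes and tests. Reads assigned to miRNA genes in the sense column were 42.2% of the file in replicate 1 and 40.9% in replicate 2, and the rest of each file named no gene. Multimapping reads were 27.5% and 29.4%, unmapped reads 23.5% and 23.0%, and reads in no feature 6.79% and 6.65%.

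Counts were divided by the total over miRNA genes of that library and given as CPM, the count scaled to a common total, with the mean and SD of the 2 libraries. The totals were 3024662 and 3464837 counts, so 1 count was 0.331 and 0.289 CPM. Intervals for shares are exact Clopper-Pearson intervals at 95% and those for ratios are exact conditional intervals. They cover counting error only, since PCR copies are not independent molecules. A gene was called detected at 2 CPM or more in both libraries. Agreement was measured across genes at 2 CPM or more in at least 1 library, on log2 of CPM plus a pseudocount of 1. Each gene with 10 or more counts in the 2 libraries together was tested with an exact two-sided conditional binomial test, adjusted by Benjamini-Hochberg at 0.05. That test compares those libraries, not conditions. With 2 libraries an exact two-sided sign-flip test cannot go below p = 0.5, so no test of levels was made. The biological coefficient of variation came from edgeR with an intercept-only model. For a gene with no count, the level that 3 counts would give is stated as its limit. Neighbouring miRNA genes on 1 strand with less than 10000 bases between them formed a cluster.

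The named genes are the 20 miRNA genes of highest mean CPM, up to 4 members of highest mean CPM in each of 20 lists, the 5 genes of 100 CPM or more with the largest ratio in each direction among those past the exact test, and the 5 clusters with the highest summed CPM. The 20 lists, this rule, the tests of the Results and the alternatives named next were fixed before the data were examined, whereas most tests of explanations were chosen after. Genes named outside this rule were chosen after the data were seen. The alternatives were unstranded counts, removal of genes whose hairpin shares a 20-base stretch with another miRNA gene, each library alone, other detection limits and pseudocounts, edgeR's TMM and DESeq2's size factors, other filters and other cluster gaps. The removal of Mir122 was added after the data were seen.

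Software was Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0. The binomial test was tested on simulated data, in which 2 libraries differed by counting error and 414 genes were tested. It recovered 56.0% of genes changed by 1.25-fold, 66.0% at 1.5-fold, 78.3% at 2-fold and 95.7% at 4-fold, and called 1.90% of 211 unchanged genes. Over 413 genes, simulated coefficients of variation of 0.2 and 0.5 were estimated at 0.19 and 0.513.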

Results

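MicroRNAs were profiled in the adrenal gland, which makes steroid hormones in its cortex and catecholamines in its medulla, from 14-day-old male mice. The mice were B6CASTF1/J, an F1 hybrid. The design has 1 group of 2 libraries and no contrast between conditions, so the question was which miRNA genes the young adrenal gland holds, at what level, and how far the 2 biological replicates differed. Replicate 1 held 7170915 reads with 3024662 sense miRNA counts, and replicate 2 held 8479789 reads with 3464837. Values below are means ± SD with n = 2 unless a replicate is named. Positions are on mm10, and intervals cover counting error only.

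By assigned counts Mir126a, the miRNA of endothelial cells, was the most abundant miRNA gene at 125189 ± 43073 CPM. It lies on chromosome 2 from 26591357 to 26591429 in an exon of Egfl7 and took 15.6% of counts in replicate 1 and 9.47% in replicate 2. Next came Mir378a at 77516 ± 8046 CPM, which lies in an intron of Ppargc1b, a regulator of mitochondrial genes, on chromosome 18 from 61397835 to 61397900. Mirlet7g, Mirlet7i and Mir143 followed at 76270 ± 7073, 51891 ± 6620 and 47423 ± 5496 CPM. Mir126a exceeded Mir378a in both libraries, by more than their counting intervals, whereas Mir378a and Mirlet7g exchanged order between the libraries. Multimapping reads, 27.5% of the file in replicate 1 and 29.4% in replicate 2, are in no gene. Genes that share sequence with others, Mir378a among them, may therefore rank too low.

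The next places were held by Mirlet7b at 38194 ± 7524 CPM, Mir10a of the Hox clusters at 37983 ± 790 and the X-linked Mir322 at 33054 ± 1389. Mir451a, a miRNA of red blood cells, was at 29477 ± 17467 CPM. Mir26b was at 28142 ± 16469 CPM and Mir375, a miRNA of neuroendocrine cells and pancreatic islets, at 28104 ± 2105. Mir335 was at 16585 ± 3169 CPM and lies on chromosome 6 from 30741299 to 30741396 in an intron of Mest, an imprinted gene. Mir127, opposite an exon of the imprinted Rtl1, was at 14531 ± 1338 CPM. The top 20 were completed by Mir122, Mir23b, Mir23a, Mirlet7d, Mir99a, Mir139 and Mir10b. Of these 20 genes, Mir122, Mir451a, Mir26b and Mir126a had the largest SD.

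**Figure D1:**
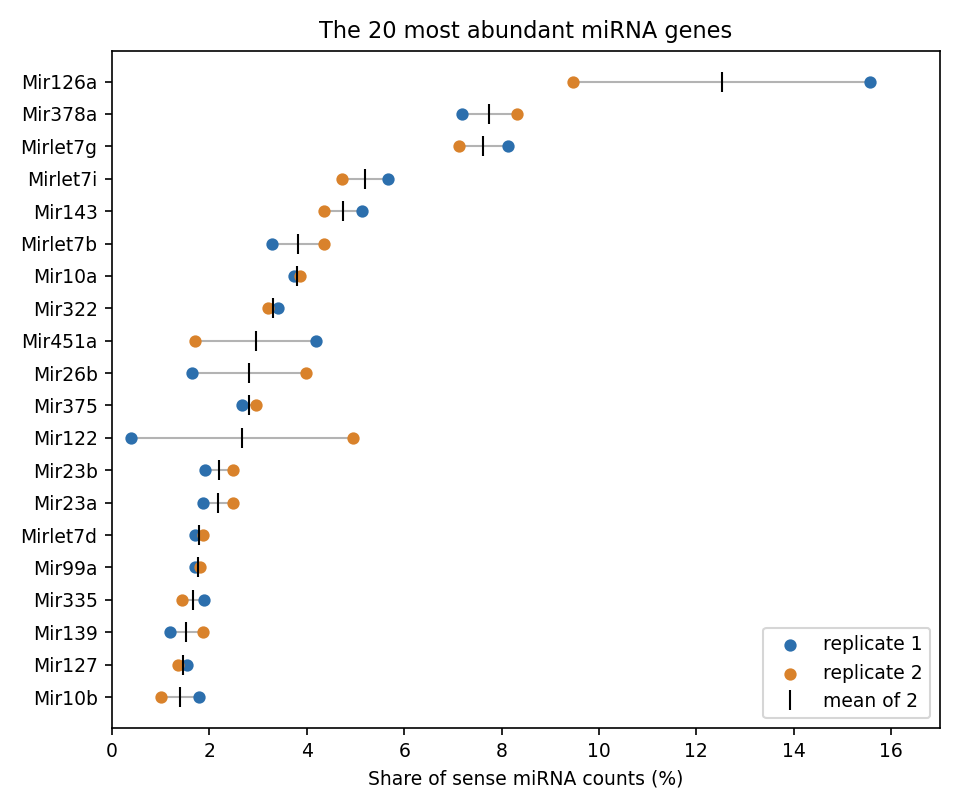
Share of sense miRNA counts (%, horizontal axis) of the 20 miRNA genes with the highest mean CPM, with a point for each library and a tick at the mean of the 2. Mir126a lies at 15.6% and 9.47%, and Mir122 at 0.379% and 4.95%.

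The single most abundant gene took 12.5% ± 4.31 of assigned counts and the 5 most abundant 38.1% ± 5.00. The 10 most abundant took 56.6% ± 3.26 and the 20 most abundant 74.5% ± 1.27. The 20 leading genes of the 2 libraries had 18 in common. At 2 CPM or more in both libraries, 364 of 2202 miRNA genes (16.5%) were detected, with 381 in replicate 1 and 392 in replicate 2. They held 99.97% of counts in each library. Mean levels reached 100 CPM in 189 genes, 1000 CPM in 81 and 10000 CPM in 23. In both libraries 1459 genes had no count. A limit of 3 counts corresponds to 0.992 CPM in replicate 1 and 0.866 in replicate 2. Of all 2202 hairpins 1087 share a 20-base stretch with another miRNA gene, among them 87 detected genes, and reads that map to several places are in no gene.

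The let-7 family, regulators of developmental timing, held the largest share among 20 fixed lists, with 20.0% ± 0.394 of counts. Mirlet7g alone made up 38.1% of it. However, 6 of the 12 measured members share a 20-base stretch with another miRNA gene, so their counts may be too low. Of its 12 measured members, 8 were higher and 3 lower in replicate 2 by the exact test (9 and 3 adjusted over the list alone). Mirlet7b was 1.32-fold higher in replicate 2 (interval 1.31 to 1.33) and Mirlet7g was 1.14-fold lower (1.13 to 1.15). The summed share was 20.2% in replicate 1 and 19.7% in replicate 2.

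The list of the imprinted Dlk1-Dio3 cluster held 6.04% ± 0.0852 of counts over 55 measured members, of which 50 were detected. Its leading members were Mir127, Mir411 at 11073 ± 904 CPM, Mir379 at 9542 ± 16.1 and Mir541 at 4478 ± 468. By the exact test 23 members were higher and 10 lower in replicate 2, with the same counts adjusted over the list alone, and 17 did not pass. The imprinted Igf2-H19 locus held 0.0146% ± 0.00573, with Mir483 at 141 ± 55.1 CPM and Mir675, in an exon of H19, at 4.83 ± 2.15. Mir483 was higher in replicate 2 and Mir675 did not pass, also adjusted over the list alone.

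The X-linked H19X cluster held 3.66% ± 0.127, with Mir322 at 90.2% of the list. Mir351 was at 2378 ± 20.0 CPM, Mir542 at 680 ± 114 and Mir503 at 334 ± 31.6. Of 7 members, 2 were higher and 2 lower in replicate 2, the same adjusted over the list alone. The Hox-cluster miRNAs held 5.35% ± 0.515, with Mir10a at 71.4% of the list. Of 6 members, 1 was higher and 4 lower in replicate 2, also adjusted over the list alone. Mir10b was 1.76-fold lower (1.74 to 1.79) and Mir196b 2.56-fold lower (2.39 to 2.73), while Mir615 was at 703 ± 49.1 CPM.

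Tissue and cell-type lists differed widely in share. Reads that map to several places are in no gene, so a share may be too low where members of a list share sequence. The endothelial list held 12.5% ± 4.31, nearly all Mir126a. Mir126b, on the opposite strand of the same locus, was at 4.62 ± 3.26 CPM. Here 1 member was higher and 1 lower, the same adjusted over the list alone. The adipose list held 7.91% ± 0.786, of which 98.1% was Mir378a. Its other leading members were Mir455 at 1020 ± 177 CPM, Mir193b at 341 ± 8.52 and Mir196a-2 at 159 ± 18.8. Of 7 members, 1 was higher and 2 lower, the same adjusted over the list alone.

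The neural and neuroendocrine list held 3.38% ± 0.237, with Mir375 at 83.2% of it. Of its 18 measured members, 14 share a 20-base stretch with another miRNA gene, and Mir375 does not. The counts of those members and the list share may therefore be too low, and the 83.2% too high. Mir7b was at 4216 ± 135 CPM, Mir137 at 849 ± 46.9 and Mir7-1 at 311 ± 10.4. Of 12 members tested, 8 were higher and 0 lower in replicate 2 (9 and 0 adjusted over the list alone). The steroidogenesis-linked list held 0.814% ± 0.0912, and 5 of its 13 members share such a stretch. Mir125a was at 2423 ± 1087 CPM, Mir320 at 1838 ± 517 and Mir214 at 792 ± 126. Of its 13 members, 6 were higher and 3 lower, with the same counts adjusted over the list alone.

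The mesenchymal and smooth muscle list held 4.94% ± 0.541, with Mir143 at 96.0% of it. Mir145a was at 1063 ± 1.46 CPM and Mir199b at 81.5 ± 35.7. Of 5 members tested, 1 was higher and 2 lower, the same adjusted over the list alone. The erythroid list held 3.16% ± 1.75, at 4.40% in replicate 1 and 1.92% in replicate 2. Mir451a was 2.44-fold lower in replicate 2 (2.42 to 2.47). Mir144 of the same cluster had a ratio of 0.980 (0.948 to 1.01) and did not pass the exact test. Of 3 members tested, 0 were higher and 2 lower, the same adjusted over the list alone, and the other fall was of Mir486, 1.56-fold (1.17 to 2.11).

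The white blood cell list held 0.374% ± 0.160, at 0.488% in replicate 1 and 0.261% in replicate 2. Mir142, a miRNA of blood cells, was at 1524 ± 988 CPM and 2.69-fold lower in replicate 2 (2.58 to 2.81). Mir146, Mir150 and Mir155 were lower by 1.57-fold, 1.30-fold and 2.05-fold, and Mir223 was 2.88-fold higher. Thus 1 member was higher and 4 lower, the same adjusted over the list alone. Mir223 was chosen after its values were seen.

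Markers of other tissues differed in level. The liver list, whose measured member was Mir122, the main miRNA of hepatocytes, held 0.379% of counts in replicate 1 (0.372 to 0.386) and 4.95% in replicate 2 (4.92 to 4.97). The kidney and epithelial list held 0.0898% in replicate 1 and 0.192% in replicate 2, led by Mir203 at 1020 ± 458 CPM. Its members Mir192 and Mir194-2, which are neighbours on chromosome 19, were 7.22-fold (5.84 to 9.01) and 2.91-fold (2.35 to 3.63) higher in replicate 2, whereas Mir200c was 1.92-fold lower (1.53 to 2.41). Of 11 members, 7 were higher and 2 lower, the same adjusted over the list alone. The striated muscle list held 0.00125% ± 0.000229, with Mir206 at 7.74 ± 2.53 CPM, and 0 of 3 members tested passed. Of the 10 measured members of the muscle list, 6 share a stretch with another miRNA gene. Reads that map to several places are in no gene, so this share may be too low and cannot show that muscle miRNAs were nearly absent. The testis X-linked list held 0.00114% ± 0.000632, with Mir547 at 8.21 ± 5.53 CPM. Of 2 members tested, 1 was higher, also adjusted over the list alone.

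Among miRNA families, the miR-30 list held 3.09% ± 0.518, the miR-26 list 2.82% ± 1.65, the miR-17~92 list 1.83% ± 0.142 and the miR-29 list 0.153% ± 0.00758. Mir26b, in an intron of Ctdsp1, made up 99.9% of the counts assigned to the miR-26 list and was 2.41-fold higher in replicate 2 (2.39 to 2.44). The other members of that list, Mir26a-1 and Mir26a-2, were at 12.2 ± 11.7 and 25.9 ± 9.50 CPM. Both hairpins share a stretch with another miRNA gene, and reads that map to several places are in no gene. Their counts and the list share may therefore be too low, and the 99.9% too high. Mir30e was at 10906 ± 2439 CPM, Mir30a at 10116 ± 2260 and Mir30d at 9242 ± 555. Mir93 and Mir17 were at 5565 ± 93.6 and 5426 ± 1179 CPM. In replicate 2, 3 of 6 miR-30 members were higher and 2 lower, 3 of 3 miR-26 members were higher, and 5 of 14 miR-17~92 members were higher and 5 lower, the same adjusted over the list alone. In the miR-29 list 1 of 4 was higher and 1 lower (0 and 1 adjusted over the list alone).

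**Figure D2:**
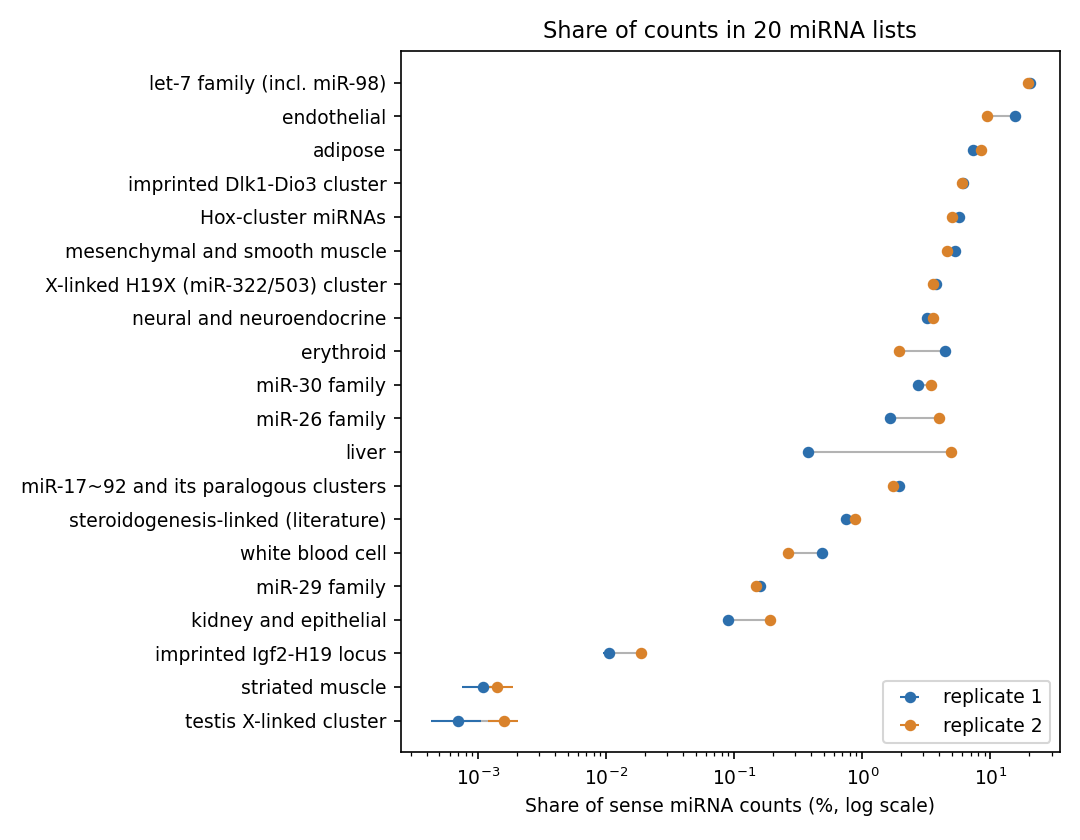
Share of sense miRNA counts (%, log scale) of each of 20 lists, with a point for each library and its exact 95% interval, which is narrower than the point for most lists. The let-7 family lies at 20.2% and 19.7%, and the liver list at 0.379% and 4.95%.

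With less than 10000 bases between neighbours, the clusters of highest level were those of Mir143 and Mir145a on chromosome 18 at 48486 ± 5498 CPM, Mirlet7b and Mirlet7c-2 on chromosome 15 at 38889 ± 7646, and the 39 genes led by Mir411 on chromosome 12 at 37743 ± 268. The 7 genes of the Mir322 cluster on the X chromosome reached 36624 ± 1274 CPM, and Mir451a with Mir144 on chromosome 11 reached 31550 ± 17496. With gaps of up to 50000 bases, Mirlet7g with Mir135a-1 came first at 76271 ± 7073 CPM. In all, 124 clusters of 2 or more genes were formed. In the Mir411 cluster the lead gene held 29.3% of the counts, against 97.8% for Mir143 and 90.3% for Mir322 in theirs.

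Mir122 showed the largest rise between the libraries, 13.1-fold higher in replicate 2 (12.8 to 13.3). It lies on chromosome 18 from 65248861 to 65248926 in an exon of a long non-coding RNA. Mir192 was 7.22-fold, Mir301 5.99-fold (5.63 to 6.38), Mir101a 3.87-fold (3.46 to 4.34) and Mir148a 3.74-fold (3.54 to 3.94) higher. Mir31 was 11.3-fold lower in replicate 2 (10 to 12.9). Mir138-1 was 5.56-fold (4.71 to 6.58), Mir107 5.11-fold (4.91 to 5.32), Mir298 4.21-fold (3.94 to 4.51) and Mir142 2.69-fold lower.

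By the exact binomial test with Benjamini-Hochberg adjustment, 229 of 413 tested genes differed between the libraries, 119 higher and 110 lower in replicate 2. This test compares those libraries, not the conditions. With unstranded counts the split was 74 higher and 139 lower, and without Mir122, an alternative chosen after the data were seen, it was 138 higher and 95 lower. Of 189 genes at 100 CPM or more, 28 differed by 2-fold or more and 161 did not, 15 higher and 13 lower in replicate 2. Across 409 genes Spearman's rho was 0.969 and Pearson's r 0.976, and genes are not independent replicates. The biological coefficient of variation was 38.0%. The chi-square of the 2 libraries, 796 per degree of freedom, served only to check that they were not 1 library deposited under both numbers. Counts on the opposite strand were 23.0% and 18.7% of the sense and antisense sum, but 0.00656% and 0.00860% over the 1721 genes with no gene on the opposite strand. In replicate 1, 95.6% of the opposite-strand counts over all genes lay in 5 annotations, Mir126b, Gm25301, Mir451b, Mir30f and Gm24083. In replicate 2, 93.6% lay in the first 4 and Gm25927. Mir126b and Mir451b lie opposite Mir126a and Mir451a, so sense reads of those 2 genes are counted again as opposite-strand reads of Mir126b and Mir451b.

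**Figure D3:**
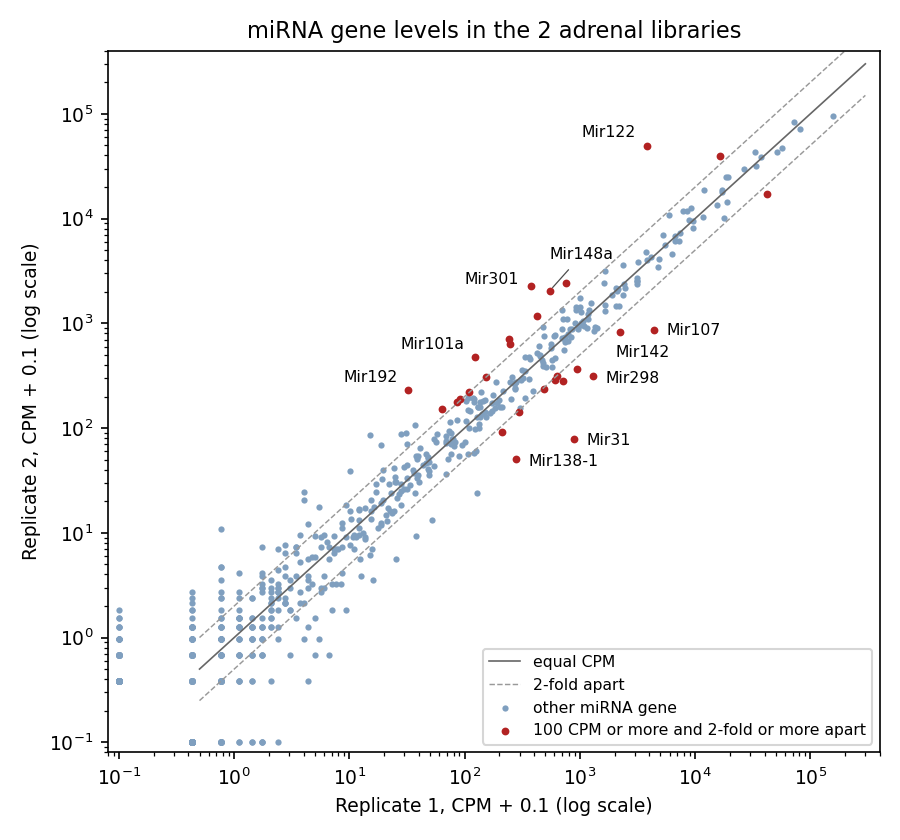
CPM of each miRNA gene in replicate 1 (horizontal) and replicate 2 (vertical), both on log axes after adding 0.1, with a solid line of equal CPM and dashed lines 2-fold apart. The 28 red points are genes of 100 CPM or more that differ 2-fold or more, including Mir122 at 3786 and 49474 CPM and Mir31 at 895 and 79.1 CPM.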

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

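The tests of other liver miRNAs, of GC content in the form given here, of dilution and of multi-copy genes were chosen only after the results they bear on were seen.

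Reads that no comparison uses are given here as values. Multimapping reads were 27.5% of the file in replicate 1 and 29.4% in replicate 2, and reads in no miRNA gene were 6.79% and 6.65%. There were no control samples to set them against. With 2 libraries, a sample far from the others and a difference between groups could not be looked for.

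Members of multi-copy families tended to have lower counts: over list members whose hairpin shares a 20-base stretch with another locus, 68 genes, the median was 17.4 CPM, against 153 CPM over the other 138 (one-sided permutation p = 0.00022). Shuffled within lists, the permutation p was 1e-05, the smallest that 100000 permutations can give. Genes were shuffled singly, but members that share a stretch are often of the same family. They are not independent, so both p-values may be too small. In the let-7 family the 6 members with a shared stretch had a median of 340 CPM and the 6 others 28034, but the members with a shared stretch also include Mir378a, at 77516 CPM, and Mir411, at 11073. A candidate explanation is that reads mapping to several loci are not assigned to a gene; lower expression of those loci stays open, and no biological explanation was tested.

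Mir122 was 13.1-fold higher in replicate 2. Its hairpin shares a 20-base stretch with 0 other miRNA genes. That check cannot bear on the rise, since reads that map to several places are in no gene and sharing would lower the count. It also covers annotated miRNA hairpins only, not the genome. Liver RNA in replicate 2 may contribute: the median log2 ratio of 12 other miRNAs listed as liver-enriched, 0.52, lay at the 99.38th percentile of random lists, with 8 of 12 higher. The 12 are not independent, since Mir101a and Mir101b are of 1 family and Mir192 and Mir194-2 are neighbours. The random lists were drawn gene by gene, so these percentiles may overstate the result. The list was written after the ratios of several members had been seen, and without Mir192, Mir148a and Mir101a, named for their large ratios, it lay at the 73.4th percentile with 5 of 9 higher, so a liver source and a difference of the gland cannot be told apart. The 9 still include Mir101b and Mir194-2, which were 2.75-fold and 2.91-fold higher. Of the most abundant members Mir30a and Mir21a were 1.38-fold and 1.49-fold higher and Mir22 1.19-fold lower, while 12 of the 12 were at 2 CPM or more in replicate 1 and 6 of the 12 stand in other lists.

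Among the 189 genes of 100 CPM or more, Spearman's rho between hairpin GC content and the log2 ratio was 0.030 (permutation p = 0.681). The fitted trend was too flat to move a gene. With its slope at the less favourable end of the 95% interval, 82.1% of the 28 genes that differ 2-fold or more stayed so (exact interval 63.1 to 93.9). This argues against a linear effect of hairpin GC content as the whole cause. The arms were not separated, so the GC content of the sequenced RNA was not tested. Dilution by liver RNA in replicate 2 would lower by 1 factor every gene that such RNA lacks. The median log2 ratio of 62 members of the neural and Dlk1-Dio3 lists was 0.18 (bootstrap interval over genes 0.07 to 0.39), so as a set these members were not lowered 2-fold. Of the 62 members 50 are of the Dlk1-Dio3 cluster, so they are not independent and the interval may be too narrow. Their directions had also been seen before the test was chosen, and it is not known here whether liver RNA lacks them. The test therefore gives no independent answer on dilution as the cause of the 13 lower genes. Over all 189 genes, the median log2 ratio was 0.0006 and 161 did not differ by 2-fold or more. A 2-fold fall common to most genes was therefore not seen. A difference between the animals or dissections stays open and was not tested.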

How the results depend on the processing

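Leaving out Mir122 was chosen only after the data were seen. Each library alone always lies within 1 SD of a mean of 2, so those runs say nothing of stability.

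Detected genes were 567 at 1 count or more in both libraries against 364, and genes differing by 2-fold or more numbered 73 against 229. Spearman's rho was 0.911 over every gene with a count. Pearson's r was 0.968 and 0.981 with pseudocounts of 0.1 and 10 CPM, 0.985 over every gene with a count and 0.967 at 10 CPM or more. The antisense share was 0.00758% over genes with no opposite-strand gene against 20.8%. Without genes sharing a stretch, the 10 and 20 leading genes took 61.2% and 77.9%.

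With unstranded counts, nearly all reads of miRNA genes that overlap another miRNA gene on the opposite strand are dropped, among them those of Mir126a, Mir378a and Mir451a. List shares then became 0.000366% endothelial, 0.282% erythroid, 0.213% adipose, 26.3% let-7, 2.50% miR-17~92, 7.59% Dlk1-Dio3, 4.99% H19X, 7.31% Hox, 0.208% miR-29, 1.08% steroidogenesis, 4.58% neural and 6.75% mesenchymal. Without genes sharing a stretch they were 23.2% let-7, 2.04% miR-17~92, 5.64% Dlk1-Dio3, 4.36% H19X, 6.36% Hox, 3.65% miR-30, 0.144% miR-29, 3.97% neural, 5.87% mesenchymal and 0.162% adipose, since Mir378a shares a stretch with Mir378c. Without Mir126a they were 22.9% let-7, 2.10% miR-17~92, 6.91% Dlk1-Dio3, 4.20% H19X, 6.14% Hox, 0.175% miR-29, 0.929% steroidogenesis, 3.86% neural, 0.000520% endothelial, 5.67% mesenchymal and 9.03% adipose. Without Mir122 they were 20.5% let-7 and 6.21% Dlk1-Dio3. Only shares that moved by 1 SD or more of the 2 libraries are given above. Lists with a large SD also shifted within it: with unstranded counts miR-26 went from 2.82% to 3.76% and liver from 2.66% to 3.48%.

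The levels of the 20 leading genes stayed within 1 SD under TMM and DESeq2's size factors, and 17 of the 20 moved with unstranded counts. Without genes sharing a stretch all the leading genes that remained rose on the smaller total, 9 by 1 SD or more and 8 by less. Among the 8 was Mir126a, from 125189 to 148878 CPM. Without Mir122 1 moved, Mir10a from 37983 to 39058 CPM, and 18 did not. The SD is that of 2 libraries, so staying within it does not mean a small shift where the libraries differ much. Without replicate 2 the liver list was at 0.379% and without replicate 1 at 4.95%. With gaps under 3000 bases the Mir411 cluster fell to 25 genes and 26348 CPM, behind those of Mir322 and Mir451a, and the other 4 leading clusters stayed within 1 SD at 3000 and 50000 bases. No paired analysis was possible because there is 1 group.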

Other observations

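The genes here were chosen after their values were seen, and no test was added for them beyond the exact test between the libraries. Mir148a, Mir152 and Mir148b were 3.74-fold, 2.93-fold and 1.65-fold higher in replicate 2. Mir301, Mir301b and Mir130a were 5.99-fold, 3.87-fold and 1.84-fold higher, while Mir130b, next to Mir301b on chromosome 16, had a ratio of 1.08 and did not pass the test. Mir107, Mir103-1 and Mir103-2 were 5.11-fold, 4.01-fold and 3.91-fold lower, and these share sequence, so their counts are uncertain. Mir200b, Mir200a and Mir429, neighbours on chromosome 4 and miRNAs of epithelia, were 5.72-fold, 6.11-fold and 3.68-fold higher, from 45, 12 and 57 counts in replicate 1, whereas Mir200c on chromosome 6 was 1.92-fold lower. Mir34a and Mir34c were 2.13-fold and 2.55-fold lower, and Mir34b, beside Mir34c on chromosome 9, was 1.75-fold higher.

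Some neighbouring hairpins differed in level or in how they changed. Mir195a was 3.22-fold higher in replicate 2 and Mir497, which lies beside it on chromosome 11, had a ratio of 0.999. Mir451a exceeded Mir144 by 20.0-fold in replicate 1 and 8.34-fold in replicate 2. Mir143 exceeded Mir145a by 44.6-fold ± 5.11 and Mir322 exceeded Mir503 by 99.6-fold ± 13.6 (n = 2). These are ratios of read counts, and their SD does not cover a bias shared by both libraries. Mir182 was at 1378 ± 527 CPM, against 83.2 ± 13.8 for Mir183 and 8.86 ± 4.77 for Mir96 in the same region of chromosome 6. Mir191 and Mir99b were close in the libraries, with ratios of 1.02 and 0.997. The X chromosome held 5.98% ± 0.280 of counts.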
